A study of Mus musculus with 6 samples.

How the data were processed

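RNA was measured by sequencing in the pancreas of 6 male mice aged 3 weeks, 3 wild-type C57Bl6/N mice and 3 mice homozygous for a null allele of OCaR1. The strain is spelled as in the labels' protocol; the labels' strain field gives C56Bl6/N for all 6 samples. OCaR1 is the product of Tmem63a, a membrane protein of acidic organelles; this link between the names is background knowledge and is not in the labels. Per the labels' protocols, RNA integrity numbers lay between 8.20 and 9.10, libraries were made from 2.5 µg of RNA after poly(A) selection, and single reads of 50 bases were sequenced. Per the submitters' processing notes, STAR 2.5.1b, Cufflinks 2.2.1, Cuffdiff and the mouse build GRCm38 were used. The annotation release, the treatment of reads that map to several places, the use of strand and the scaling and dispersion settings of Cuffdiff are not given in the sources used here.

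The deposited file is a gene table in the format of Cuffdiff with 12016 rows. For each gene the authors give 1 FPKM value (fragments per kilobase of transcript, scaled to library size) per genotype, which combines the 3 libraries, so no value of a single mouse was available and no SD, standard error or n of its own stands beside any level. Per the file headers the table also holds the log2 fold change of wild type over knockout, the test statistic (a score), and the authors' p-value and q-value. Depth is unknown, since the deposited FPKM values are 1 per genotype and no counts were used here. No binomial interval or detection floor is given for that reason, and a value listed at 0 may be a failed estimate. Every row has a value above 1 FPKM in at least 1 genotype (the lowest such maximum is 1.00006), so genes below that level in both genotypes were not analysed here. The columns of single samples numbered 0.

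The planned test on values per library on log2 values with a pseudocount of 0.5 could not be made from this table. The choice written down before the data were examined for that case was followed: a gene was called changed where the authors' deposited table marks it significant, at q under 0.05, and no test of differential expression was added. The smallest p in the table is 5e-05 and is shared by 394 genes, all called, so these genes cannot be ranked by p. Adjusting the deposited p-values again over the 11478 tested genes of the table gave 867 calls in place of 866, and the deposited q at the smallest p was 1.05 times the recomputed value. The 538 genes marked as not tested were left out of every count.

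Fold changes were recomputed from the deposited FPKM values as knockout over wild type, with no pseudocount, so that positive log2 values are higher in the knockout. The deposited fold change differed from these by more than 0.01 on the log2 scale in 3 rows (Nhej1, Pik3c2g and Srp54b), of which Pik3c2g is called; none of them is used as an example. A value under 0.01 FPKM was treated as listed at 0, and 37 tested genes with such a value got no fold change. Intervals of the locus column count starts from 0 and were shifted to start at 1; 3502 rows share their interval with another row, where reads of overlapping or neighbouring genes could be divided between them. Among the genes named below, Tmem63b, Herpud1, Shmt2, Cd74, Dbp and Tcf7 also share their interval, besides those marked so beside their values. Of the gene identifiers, 11958 were found in GENCODE release M21 of the same build, and 7006 have the same start there.

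Before the data were examined, 34 gene lists were fixed (acinar secretion, organellar calcium, lysosome, stress, metabolism, and markers of the other cell types a pancreas sample can hold). A list with at least 3 tested members was described by its called members and by the percentile of its median log2 fold change among 10000 random lists of the same size, matched on mean FPKM in 20 bins. This percentile describes these 2 sets of group values and is not a p-value, since genes are not replicates; a list was said to stand apart below percentile 2.5 or above percentile 97.5. Counts of called members are given with the q of the whole table and again after Benjamini-Hochberg adjustment of the deposited p-values over the list alone. On simulated ratios made by shuffling the 11441 finite values within bins, 6.0% of 100 unshifted lists of 20 genes stood apart. Of lists shifted by 0.3 on the log2 scale 99.0% did, and of lists shifted by 0.6 100% did. Shuffling removes any shared movement of the genes of a list, and lists of other sizes were not simulated. These rates therefore do not carry over to the lists described below.

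Genes named in the text follow a rule written before the data were examined: Tmem63a and its family, Nnt, insulin, glucagon, amylase, Cpa1, Pnlip, Tpcn1 and Tpcn2 where measured, the 12 called genes with the largest rise and the 12 with the largest fall, and up to 4 members of each list with the smallest p, ties going to the larger fold change. Some genes that this rule names are not reported here. Called genes listed at 0 in 1 genotype have no fold change and are named apart. Genes named outside this rule were chosen after their values were seen, most of them to complete a count of 5 or fewer: Cela1, Sycn, 1810009J06Rik, Npc2, Nupr1, Acta2, Nr4a1, Egr1, C130074G19Rik and those of the closing section. Tmem63c, Tpcn2 and the amylase genes Amy2a5 and Amy2b were not analysed here. The share of called genes within 10 Mb of Tmem63a was set against the remaining tested genes with Fisher's exact test, two-sided. Alternatives covered pseudocounts, the FPKM minimum, the q threshold, scaling, and genes that share an interval. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.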

Results

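Gene expression was compared between the pancreas of 3 male mice that lack OCaR1 (encoded by Tmem63a) and that of 3 male wild-type mice, all 3 weeks old. The pancreas consists mainly of acinar cells, which store digestive enzymes in zymogen granules, and this was visible in the RNA: the digestive enzyme genes of the fixed list made up 58.1% of the summed FPKM of the knockout group and 62.5% of that of the wild-type group. The levels below are the authors' group values, 1 per genotype, in FPKM, and where 2 values stand side by side the knockout comes first. The table carries no spread between mice, so no replicate error can be given. Whether a difference exceeded that spread rests on the q-value of the authors' Cuffdiff test, with 0.05 as the threshold. A gene is said to be called, to rise or to fall where it passed that threshold.

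The targeted gene was lower in the knockout. Tmem63a (ENSMUSG00000026519, protein-coding, GRCm38 chromosome 1, 180942344 to 180975112) stood at 4.91 FPKM in the knockout and 18.3 FPKM in wild type, so that 26.8% of the wild-type level remained. Its log2 fold change was -1.90, with q = 0.00152 in the authors' deposited table. A gene-level value does not show which exons the remaining reads came from. Its paralog Tmem63b had 19.3 FPKM in the knockout and 20.5 FPKM in wild type and was not called (q = 0.879 in the authors' deposited table). The family list of these 2 tested genes thus held 1 call, also adjusted over the list alone. Nnt, the mitochondrial transhydrogenase whose deletion distinguishes the C57BL/6J substrain, stood at 12.2 FPKM in the knockout and 14.9 FPKM in wild type (q = 0.0561 in the authors' deposited table). With Cyfip2 it makes up the substrain list of 2 tested genes, of which 0 were called by Cuffdiff and 1, Nnt, was lower adjusted over the list alone (1 had an unadjusted p under 0.05).

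Of 11478 tested genes, the authors' deposited table called 866 (7.54%): 482 were higher and 384 lower in the knockout. The balance turned among more abundant genes: with at least 5 FPKM in either group, 229 were called higher and 268 lower. The median size of the called changes was 0.60 on the log2 scale (1.51-fold), and 107 genes rose and 38 fell by at least 1 on that scale. The median over all tested genes was -0.03, and list medians are to be read against it. The largest falls were in genes of visceral smooth muscle, Actg2 (smooth muscle gamma actin, 16.6-fold lower, from 14.6 to 0.878 FPKM) and Cnn1 (calponin, 11.1-fold lower). Metabolic and stress genes were also among them: Pdk4, an inhibitor of pyruvate oxidation, was 4.03-fold lower, the stress-induced pseudokinase Trib3 3.27-fold lower and the hormone gene Fgf21 2.74-fold lower. Kctd15 (4.21-fold), the apolipoprotein gene Apoa2 (3.78-fold), the phosphatase gene Dusp23 (2.95-fold) and the immunoglobulin segments Igkv14-111 (6.42-fold) and Igkv16-104 (3.58-fold) were among the 12 largest falls, as was Tmem63a. Apoa2 and Dusp23 lie within 10 Mb of Tmem63a.

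Among the 12 largest rises, 6 were immunoglobulin variable segments, led by Igkv12-89 (16.1-fold higher, from 1.08 to 17.4 FPKM) and followed by Igkv12-44 (11.2-fold), Igkv1-135 (10.6-fold), Ighv1-55 (9.09-fold), Igkv1-117 (6.48-fold) and Ighv7-3 (6.06-fold). The others were the transcribed pseudogene C920009B18Rik (46.2-fold higher, from 0.0380 to 1.76 FPKM, in an interval shared with another gene), the innate RNA sensor Tlr13 (17.4-fold), the transcription factor gene Mitf (8.52-fold, from 0.619 to 5.27 FPKM), Erdr1 (5.84-fold), the lipogenic regulator Thrsp (5.59-fold) and the chemokine gene Ccl24 (5.21-fold). A further 6 called genes were listed at 0 in wild type, for which no fold is given: Ifi202b, an interferon-inducible gene, had 1.53 FPKM in the knockout, and the immunoglobulin segments Igkv6-13, Igkv6-14, Ighv2-9-1, Igkv8-28 and Ighv1-76 had between 1.45 and 4.86 FPKM. Immunoglobulin segments of the same family are close in sequence, so reads could be divided between such members.

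**Figure D1:**
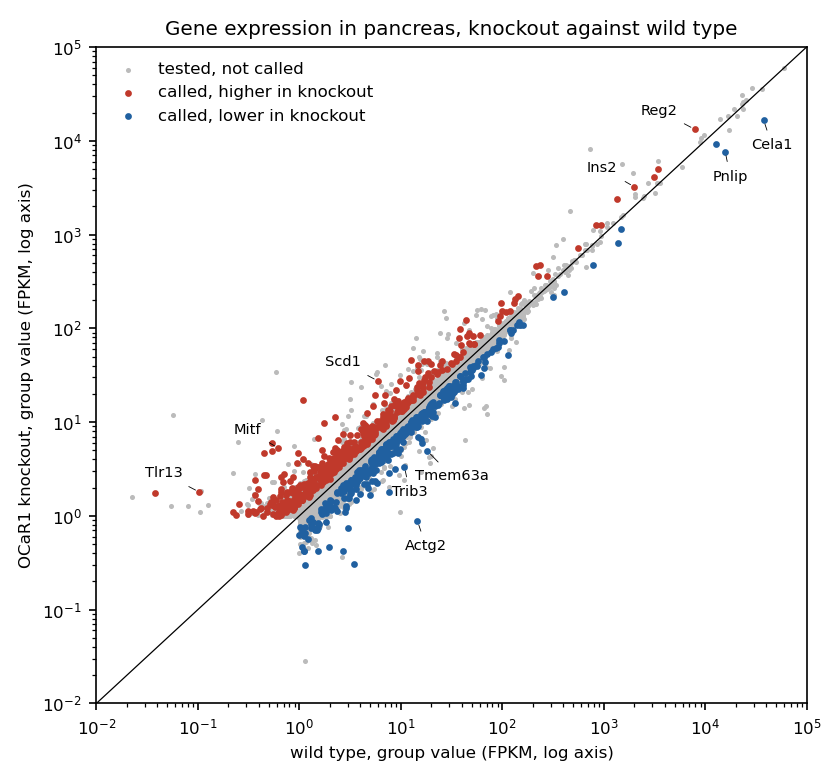
Group value of each tested gene in the OCaR1 knockout (vertical log axis, FPKM) against wild type (horizontal log axis, FPKM), 1 point per gene; red and blue points were called higher (482 genes, of which 6 listed at 0 in wild type are not drawn) and lower (384 genes) in the knockout, grey points were not called, and the diagonal marks equal values. Tmem63a lies at 18.3 FPKM in wild type and 4.91 FPKM in the knockout, and genes with a value under 0.01 FPKM in either group are left out.

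The cargo of the zymogen granules changed in single genes and in both directions. Pancreatic lipase (Pnlip) fell from 15748 to 7662 FPKM (2.06-fold, q = 0.0407 in the authors' deposited table) and Cela1, an elastase gene, from 37728 to 16591 FPKM (2.27-fold, q = 0.0487), while the trypsinogen genes Prss1 (2.10-fold), Prss3 (2.11-fold) and Gm5771 (2.80-fold) and the trypsin inhibitor gene Spink3 (1.31-fold) rose. Also called were Sycn, which encodes the granule protein syncollin (9338 FPKM in the knockout and 12703 FPKM in wild type, in an interval shared with another gene), and 1810009J06Rik (1.58 and 0.910 FPKM). The carboxypeptidase gene Cpa1 stood at 21972 FPKM in the knockout and 23509 FPKM in wild type (q = 0.916 in the authors' deposited table). Of 32 tested members of the list, the authors' deposited table called 5 higher and 3 lower (6 and 3 adjusted over the list alone). The list median was 0.09, at percentile 99.5 of matched random lists. Trypsinogen genes are close paralogs whose reads could be divided between them.

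The machinery of granule exocytosis and secretagogue signalling held few calls. Of 32 exocytosis genes, the authors' deposited table called Stx2 (2.15-fold) and Stx4a (1.39-fold), both syntaxins, higher and none lower (2 and 0 adjusted over the list alone). The list median was 0.01, at percentile 81.9. Rab27b, a granule GTPase, had 5.31 and 6.46 FPKM in the knockout and wild type (q = 0.152 in the same table). Among 17 genes of secretagogue receptors and signalling, the calcineurin subunit gene Ppp3ca fell (log2 fold change -0.58) and the bombesin receptor gene Grpr rose (0.58). Adjusted over the list alone there were also 1 higher and 1 lower, and the median was -0.06, at percentile 39.4.

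Transcripts of organellar calcium channels were not called in either direction. Of 11 tested endolysosomal and endoplasmic reticulum channel genes and their partners, the authors' deposited table called 0 by Cuffdiff (0 adjusted over the list alone, 2 at an unadjusted p under 0.05). Their median of -0.14 lay at percentile 12.2. Tpcn1, a channel of endolysosomes, had 4.77 FPKM in the knockout and 5.23 FPKM in wild type (q = 0.614 in the authors' deposited table), and Itpr1, an inositol trisphosphate receptor gene, 1.25 and 1.07 FPKM (q = 0.298). Genes of calcium entry were among those that changed: Orai2, a plasma membrane calcium channel gene, fell by 0.59 on the log2 scale, and Saraf, which encodes an inhibitor of store-operated entry, fell 1.33-fold in an interval shared with another gene. These were the 2 calls, both lower, of 25 tested calcium pump, entry and buffering genes (0 higher and 3 lower adjusted over the list alone; median -0.03, percentile 57.1). Among members with at least 5 FPKM in either group the list lay at percentile 1.78. The store sensor gene Stim1 had 5.82 and 7.22 FPKM and just missed the threshold, at q = 0.0501 in the authors' deposited table.

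Of 42 tested lysosomal genes, the authors' deposited table called 5 higher and none lower (8 and 1 adjusted over the list alone). The median was 0.05, at percentile 98.7. The called genes were Mitf, Ctss (the cathepsin S gene, 2.35-fold), Lipa (lysosomal lipase, 1.36-fold), Tpp1 (a lysosomal peptidase, 1.27-fold) and the cholesterol-binding Npc2 (8.36 and 6.69 FPKM). Ctss also belongs to the antigen presentation list, and macrophage genes were higher in the same group (list median 0.80). The vacuolar ATPase list held 1 call of 19, Atp6v1b2 (1.35-fold higher; 0 adjusted over the list alone; median 0.07, percentile 96.2). In the autophagy list 1 of 33 was called, the kinase gene Ulk1 (1.24-fold lower; 0 adjusted over the list alone; median -0.07, percentile 24.6).

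Genes of the unfolded protein response were lower in the knockout. The authors' deposited table called 10 of 33 lower and none higher (12 and 0 adjusted over the list alone). The median of -0.20 lay below all 10000 random lists. Trib3 fell from 10.9 to 3.32 FPKM, Chac1, a glutathione-degrading enzyme gene induced by stress, from 61.3 to 31.6 FPKM, the stress sensor gene Ern1 from 14.2 to 9.01 FPKM, and Herpud1, a component of endoplasmic reticulum degradation, from 314 to 213 FPKM. Of 24 tested amino acid supply genes, 6 fell and none rose in the authors' deposited table (10 lower and 1 higher adjusted over the list alone). Their median of -0.34 also lay below all 10000 random lists. They included Fgf21, the cystine transporter gene Slc7a11 (2.55-fold lower), Mat1a, which makes S-adenosylmethionine (1.65-fold), and the mitochondrial serine enzyme gene Shmt2 (log2 fold change -0.59). Of 11 acinar transcription factor genes, 3 fell in the authors' deposited table (6 lower and 1 higher adjusted over the list alone; median -0.31, percentile 0.12). These were Ptf1a, the central acinar factor, from 40.9 to 27.2 FPKM, Gata4 from 18.9 to 13.0 FPKM and Nr5a2 from 13.6 to 10.6 FPKM. Xbp1 had 246 FPKM in the knockout and 304 FPKM in wild type without a call (q = 0.105 in the authors' deposited table). Fat cell, macrophage, islet and stromal genes were higher in the same knockout group (list medians 1.06, 0.80, 0.60 and 0.37).

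Genes linked to acinar stress and injury were mostly higher. Of 27 tested members, the authors' deposited table called 11 higher and 2 lower (13 and 2 adjusted over the list alone). The median of 0.45 lay above all 10000 random lists. The secreted lectin genes Reg3g (2.01-fold, from 237 to 478 FPKM) and Reg3a (1.80-fold, from 1342 to 2414 FPKM) and the adhesion receptor gene Cd44 (1.78-fold) rose, and the stress cytokine gene Gdf15 (2.00-fold) and the stress-induced Nupr1 (814 and 1391 FPKM) fell. Of the 27 members, 7 belong to another list as well. Of 12 duct genes, 6 of which are held by another list, 1 was called, Sox9 (1.48-fold higher; 2 higher adjusted over the list alone; median 0.19, percentile 99.1). Without members of another list the duct genes lay at percentile 90.9, and with at least 5 FPKM in either group at 92.0. The duct keratin gene Krt19 had a log2 fold change of 0.26 without a call (q = 0.353 in the authors' deposited table). Macrophage, fat cell and stromal genes were higher in the same group (list medians 0.80, 1.06 and 0.37).

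Markers of most other cell types in the samples were higher in the knockout. Most islet genes rose, among them Ins2 from 1998 to 3231 FPKM (1.62-fold), Ins1 from 142 to 222 FPKM (1.56-fold), the glucagon gene Gcg from 226 to 360 FPKM (1.59-fold), and the islet phosphatase gene G6pc2 2.31-fold. Of 23 tested islet genes the authors' deposited table called 15 higher and none lower (15 and 0 adjusted over the list alone; median 0.60, above all 10000 random lists). Of 18 macrophage and monocyte genes, 14 were called higher and none lower in the authors' deposited table (17 and 0 adjusted over the list alone; median 0.80, above all 10000 random lists). Among them were Lyz2, a lysozyme gene (2.38-fold), Mpeg1 (2.51-fold) and Emr1 (2.33-fold). All 6 tested genes of MHC class II presentation rose in the authors' deposited table, including Cd74 (2.49-fold), H2-Aa (2.81-fold) and H2-Eb1 (2.70-fold). Adjusted over the list alone there were also 6, and the median was 1.28, above all 10000 random lists. Of 11 fat cell genes, 8 were called higher and none lower (10 and 0 adjusted over the list alone; median 1.06, above all 10000 random lists), for example the adipokine genes Retn (4.92-fold) and Cfd (2.73-fold) and Car3 (2.63-fold).

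Stromal and vascular lists had smaller medians. Of 27 stellate cell and fibroblast genes, 11 were called higher and 2 lower in the authors' deposited table (14 and 2 adjusted over the list alone; median 0.37, above all 10000 random lists). The matrix genes Mgp (1.79-fold), Postn (1.63-fold) and Tgfbi (1.53-fold) rose. The muscle filament gene Des (2.31-fold) and the actin gene Acta2 (11.5 and 17.1 FPKM) fell. Endothelial genes had 6 of 15 called higher and none lower (8 and 1 adjusted over the list alone; median 0.38, above all 10000 random lists), among them Cdh5 (log2 fold change 0.58) and Pecam1 (1.45-fold). Red cell genes had 2 of 6 called higher, the globin genes Hba-a1 (1.29-fold) and Hba-a2 (1.30-fold), which are near-identical copies (3 higher adjusted over the list alone; median 0.31, percentile 98.5). Among 5 B cell and plasma cell genes, Igj was called (3.03-fold higher; 1 adjusted over the list alone; median 0.54, percentile 98.0, and 97.2 with a pseudocount of 0.5). Cuffdiff called 0 of 3 neutrophil genes, with 3 higher adjusted over the list alone and 3 at an unadjusted p under 0.05 (median 0.74, percentile 98.2). The T cell list had 1 tested gene, Tcf7, at 0.821 and 1.61 FPKM without a call, and 0 at an unadjusted p under 0.05 or adjusted over the list alone.

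Muscle genes and those of neighbouring organs went the other way. The muscle and nerve list had 4 of 5 tested genes called lower in the authors' deposited table (4 adjusted over the list alone; median -1.21, below all 10000 random lists): Actg2, Cnn1, Des and Myh11, the smooth muscle myosin gene (2.21-fold). Of 4 tested intestine and liver genes, Alb, the albumin gene, was called lower (1.86-fold, from 1.39 to 0.746 FPKM; 1 adjusted over the list alone; median -0.52, percentile 0.24).

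**Figure D2:**
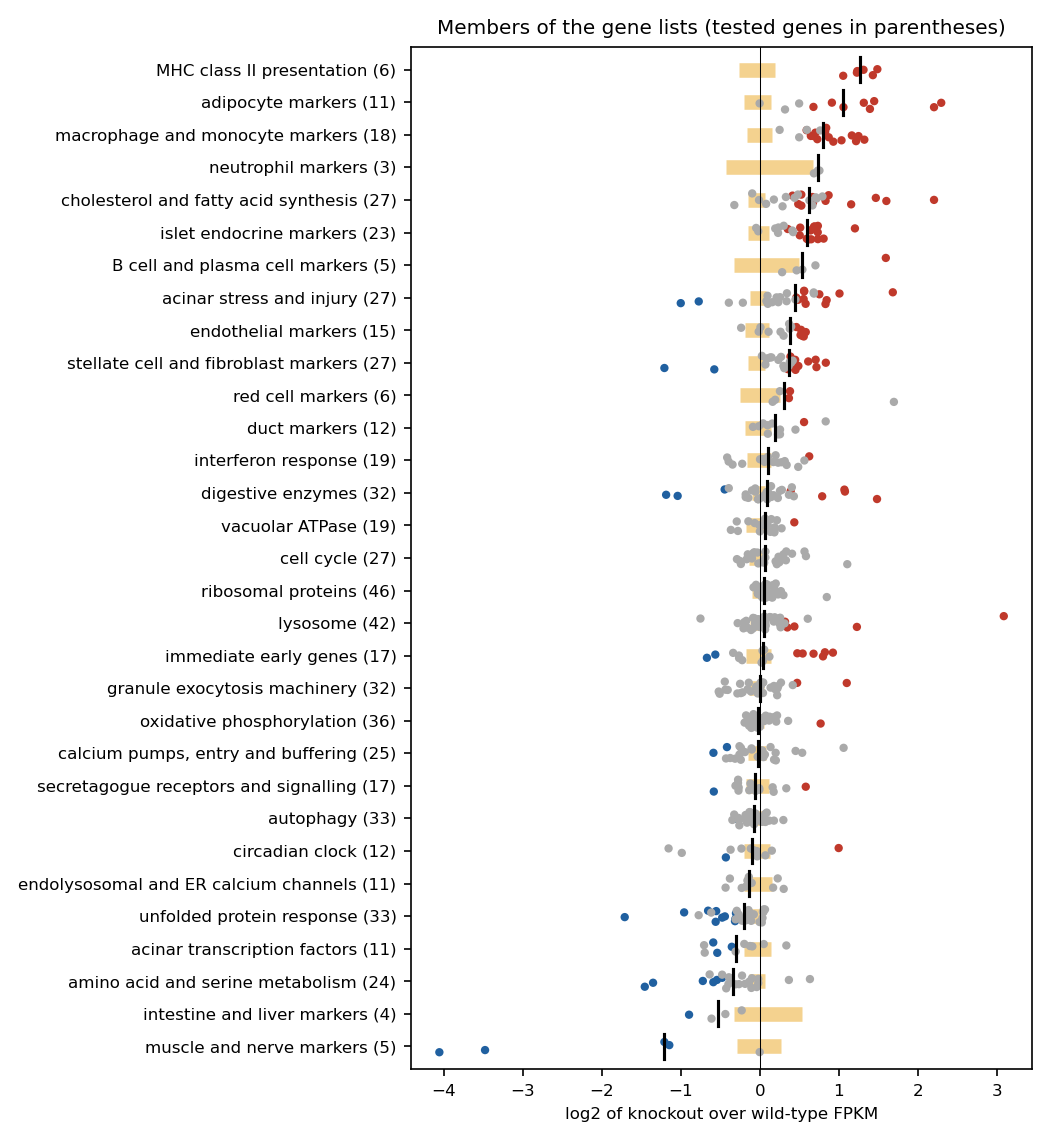
Log2 of knockout over wild-type FPKM (horizontal axis) for each tested member of the 31 lists with at least 3 tested genes, 1 point per gene, with the list's median as a black bar and the central 95% of medians of 10000 matched random lists as a yellow bar; red and blue points were called higher and lower, grey points were not called. The medians of fat cell genes (1.06) and macrophage genes (0.80) lie right of the yellow bars and those of the muscle and nerve genes (-1.21) and amino acid genes (-0.34) lie left of them.

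Genes of cholesterol and fatty acid synthesis were higher in the knockout. The authors' deposited table called 13 of 27 higher and none lower (18 and 0 adjusted over the list alone). The median of 0.63 lay above all 10000 random lists. Scd1, the main fatty acid desaturase, rose from 5.95 to 27.5 FPKM (4.62-fold), its paralog Scd2 from 9.90 to 27.4 FPKM (2.77-fold), and the fatty acid synthase gene Fasn 2.23-fold. Fat cell genes, which include Scd1, were higher in the same group (list median 1.06).

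The remaining lists held few calls or calls in both directions. Immediate early genes had 6 of 17 called higher and 2 lower in the authors' deposited table (6 and 4 adjusted over the list alone; median 0.04, percentile 80.1). Junb (1.90-fold), Zfp36 (1.77-fold), Dusp1 (1.74-fold) and Klf6 (1.60-fold) were among the rises, and Nr4a1 (1.05 and 1.67 FPKM) and Egr1 (1.19 and 1.76 FPKM) fell. Clock genes had 2 calls of 12, Nfil3 (2.00-fold higher) and Nr1d2 (1.35-fold lower), the same adjusted over the list alone (median -0.09, percentile 25.7, and 0.18 among members with at least 5 FPKM in either group). Dbp had 22.6 FPKM in the knockout and 50.3 FPKM in wild type without a call (q = 0.214 in the authors' deposited table). Interferon response genes had 1 call of 19, Gbp2 (1.54-fold higher; 1 adjusted over the list alone; median 0.10, percentile 94.1). Among 36 respiratory chain genes, 1 was called, higher, in the authors' deposited table (1 adjusted over the list alone). The median of the list was -0.02 and its mean 0.02, at percentile 61.9. Cuffdiff called 0 of 27 cell cycle genes (1 at an unadjusted p under 0.05; median 0.07, percentile 94.05, and 99.55 with at least 5 FPKM in either group). It called 0 of 46 ribosomal protein genes (2 at an unadjusted p under 0.05; median 0.06, percentile 98.4, and 95.7 with at least 5 FPKM in either group). Adjusted over the list alone there were 0 in either list. In all, 20 of the 31 lists stood apart from matched random lists, 15 above and 5 below.

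Sequence near a targeted gene can differ from that of the control strain, so called genes were counted around Tmem63a on chromosome 1. Within 10 Mb on either side, 14 of 107 tested genes (13.1%) were called in the authors' deposited table, against 851 of 11370 (7.48%) elsewhere (Fisher's exact test, two-sided, p = 0.0403). Nearer to the gene the share was lower: by Fisher's exact test, 1 of 48 genes within 5 Mb was called (2.08%, p = 0.264), C130074G19Rik (3.70 and 2.02 FPKM). Within 20 Mb it was 22 of 196 (11.2%, exact p = 0.0553), against 7.47% elsewhere. Within 10 Mb without genes that share an interval it was 12 of 75 (16.0%, exact p = 0.0682), against 9.28% elsewhere, with the same odds ratio of 1.86 as with all genes. Called genes within 10 Mb included Apoa2 (171225054 to 171226379), Dusp23 (172630764 to 172632962) and Ifi202b (173962568 to 173982744), the last listed at 0 in wild type. Apart from C130074G19Rik, the called genes within 10 Mb all lay at lower coordinates than Tmem63a, at distances from -9.90 to -6.94 Mb. Neighbouring genes are not independent, and the p-value treats them as if they were.

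**Figure D3:**
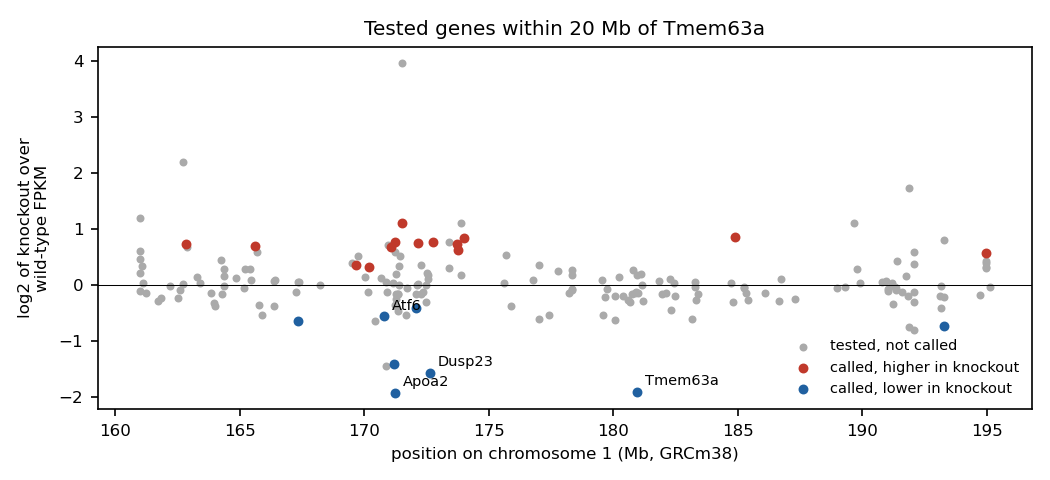
Log2 of knockout over wild-type FPKM (vertical axis) against position on chromosome 1 of GRCm38 (horizontal axis, Mb) for tested genes within 20 Mb of Tmem63a, 1 point per gene; red and blue points were called higher and lower, grey points were not called, and Ifi202b, listed at 0 in wild type, is not drawn. Within 5 Mb of Tmem63a 1 of 48 genes was called, and within 10 Mb 14 of 107 were.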

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

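No paired analysis was possible because the table holds 1 value per genotype. For the same reason leaving out a mouse, library weights, limma with or without trend, count models, an estimated correlation and other splits of the mice gave no value, and depth cannot be judged. Leaving out shared intervals, immunoglobulin segments or members of another list, and adjusting p again, were chosen after seeing the data. The table already starts at 1 FPKM, so that filter removed no gene. The 866 calls became 522 (311 higher, 211 lower) at q under 0.01, 497 with at least 5 FPKM in either group (229 higher, 268 lower), and 151 with at least 1 on the log2 scale (113 higher, which include the 6 genes listed at 0 in wild type, and 38 lower); fewer genes can pass by construction. The balance of directions turned at 5 FPKM, where 46.1% were higher against 55.7% of all calls. There were 1119 at q under 0.1, 867 adjusted again, 783 without shared intervals and 849 without immunoglobulin and T cell receptor segments. A pseudocount cannot turn the direction of a ratio of 2 values, and median centring and a trimmed rescaling without the 50 most abundant genes shift all genes by 1 small constant, so these settings test no call. Among 148 named genes, 20 called ones lost their call at q under 0.01; Tmem63a ranged from -1.90 to -1.71 on the log2 scale. Of 31 lists 20 stood apart, against 19 of 27 at 5 FPKM and 18 of 30 without members of another list. With fewer than 3 members left, the neutrophil, B cell, intestine and liver (all apart before) and interferon lists gave no value at 5 FPKM, nor did the neutrophil list without members of another list. Lists measured but no longer apart were the B cell genes with a pseudocount of 0.5 (percentile 97.2) or 1 (96.7) or without genes that share an interval (95.02), the duct genes at 5 FPKM (92.0) or without members of another list (90.9), and the ribosomal protein genes at 5 FPKM (95.7) or without shared intervals (95.025). Lists that newly did were, at 5 FPKM, calcium pumps (1.78), vacuolar ATPase (97.8), clock genes (0.18) and cell cycle (99.55). Without shared intervals the vacuolar ATPase (98.3) and interferon genes (97.8) newly did, and with a pseudocount of 1 the interferon genes (97.6). The share of calls near Tmem63a was below that elsewhere within 5 Mb (2.08%). It missed the threshold of Fisher's exact test within 20 Mb (11.2%) and without shared intervals (16.0%, against 9.28% elsewhere, at an odds ratio of 1.86 as with all genes). For the lists and the shares near Tmem63a the cause was not tested.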

Other observations

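Lists called unseen here were drawn up after the largest changes had been looked at, from genes whose own values had not been. The test in the chromosome 1 window and that of the falls against added fat were chosen after the result was seen, and the shares around Tmem63a, planned before, were set against strain sequence only then. Genes of fatty acid oxidation were lower in the knockout: of 26 tested unseen members, 8 fell and none rose in the authors' deposited table (10 lower adjusted over the list alone). Their median was -0.23, at percentile 0.02 of matched random lists. They included Hadh (from 40.8 to 23.2 FPKM), Eci2 (33.7 to 20.8 FPKM), Acaa2 (16.2 to 10.2 FPKM) and Acadl (14.1 to 8.96 FPKM), all enzymes of fatty acid breakdown. All 24 unseen ATF4 targets and tRNA synthetase genes lay below 0, with 11 called lower in the authors' deposited table (15 adjusted over the list alone). Their median of -0.41 lay below all 10000 random lists, and Gars (51.6 to 37.3 FPKM), Nars (80.2 to 60.1 FPKM) and Cth (44.0 to 28.8 FPKM) were among the called.

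Immunoglobulin genes were mostly higher in the knockout: of 53 tested, 42 had the higher value there, and the authors' deposited table called 15 higher and 2 lower. Of 17 tested transcripts of the mitochondrial genome, looked at after their values were seen, the authors' deposited table called 4 higher and none lower, and 16 had the higher value in the knockout. The called were mt-Co1 (1250.1 against 937 FPKM), mt-Nd2 (711 against 563 FPKM), mt-Rnr1 (67.2 against 47.7 FPKM) and mt-Rnr2 (51.7 against 35.4 FPKM). Of 13 unseen glucocorticoid targets, 2 were called higher and 2 lower in the authors' deposited table (2 and 3 adjusted over the list alone). Sult1a1 (8.16 and 4.15 FPKM in the knockout and wild type, in a shared interval) and Zbtb16 (4.17 and 2.17 FPKM) rose, and Mt1 (1141 and 1466 FPKM) and Mt2 (478 and 783 FPKM) fell. The median of this list was -0.00 and its mean 0.03, at percentile 65.1.

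On chromosome 1, the window of 10 Mb that starts at 170 Mb had 15 of 71 tested genes called (21.1%), which ranked 3 of the 205 windows with at least 20 tested genes; it was singled out after its values were seen. Sequence from another strain around the targeted allele is a candidate explanation, and Ifi202b, listed at 0 in wild type, lies there. Within 5 Mb of Tmem63a, where linkage is tightest, 2.08% of tested genes were called, against 7.56% elsewhere (Fisher's exact test, two-sided, p = 0.264). This difference cannot decide, and no sequence variants were analysed here, so strain sequence stays open. Immune genes that move with the macrophage genes cannot be told apart from it either: 5 of the 15 called genes were lower in the knockout, 7.04% of the window against 3.32% elsewhere (Fisher's exact test, two-sided, p = 0.0887). An effect of the loss of OCaR1 on these genes was not tested.

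Islet, macrophage, fat, endothelial and stromal genes were higher in the knockout. A smaller share of acinar RNA would raise the genes of every other cell type alike, and smooth muscle did not follow. The 12 unseen smooth muscle genes had a median of -0.26 and an upper quartile of -0.02, against a lower quartile of 0.33 for islet genes. That list was drawn up after falls of other smooth muscle genes had been seen, so its fall was foreseeable. It argues only against 1 common factor for all cell types. Whether a smaller acinar share raised the islet, macrophage, fat, endothelial and stromal genes stays open. More fat around the pancreas in the knockout samples is a candidate source of the fat cell genes, as 15 unseen ones had a median of 0.50, and the abundant Car3 (44.8 and 17.0 FPKM) and Cfd (40.7 and 14.9 FPKM) rose. The unseen fat cell list was drawn up after rises of other fat cell genes had been seen, so its rise was foreseeable too. Less smooth muscle tissue cannot be told apart from a change within it, since the lower quartile of the unseen genes, -0.52, lay beyond the -0.3 set as a bound and their median did not reach it. More islet, immune or fat cells through the genotype stays open as untested.

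Genes of the stress response and of fatty acid breakdown were lower in the knockout and lipid synthesis genes higher. Added fat would lower the genes of other cells by 1 common factor. The digestive enzyme genes (median 0.0925, interquartile range 0.37) lay above the amino acid genes by 0.43 and the unseen ATF4 targets by 0.50. By that measure this narrowly argues against added fat for these. It rests on the median of single genes: as a share of summed FPKM, the digestive enzyme genes were lower in the knockout (58.1% against 62.5%). For the unfolded protein response (0.30) and fatty acid oxidation genes (0.32) the gap was within the interquartile range, which is a spread of single genes. The medians of these lists, -0.20 and -0.23, lay below the central 95% of medians of matched random lists, which began at -0.12 and -0.15. Those random lists were drawn from all tested genes, with the fat cell genes that rose among them. They restate the fall and cannot decide on added fat, which stays open as a cause for the unfolded protein response and fatty acid oxidation genes. A difference in feeding between the groups is a candidate explanation, since the unseen fatty acid oxidation genes, at -0.23, lay below matched random lists as it predicts. A lower ATF4 programme is a hypothesis for the stress genes that the unseen targets, at -0.41, also follow. Genotype stays open as an untested cause of either, and feeding and the hour of collection are not given in the sources used here. Both unseen lists were drawn up after falls of stress and metabolic genes had been seen, so their falls were foreseeable.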
